A study of Mus musculus with 54 samples.

How the data were processed

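Messenger RNA was measured by bulk MARS-seq in 54 samples of mouse cells, in 18 groups of 3: DOX at 6 times, DOX followed by withdrawal, DOX with LPA at 3 times, 2 iTSC clones, 3 established TSC lines, ESC, MEF and XEN. Per the labels' protocols, RNA was extracted with RNeasy mini kits and cells were grown on MEF feeders. Per the submitters' processing notes, reads were trimmed with cutadapt (version not stated), aligned to mm10 with STAR 2.4.2a and normalized with DESeq2 (version not stated). The handling of molecular identifiers, the counter, its strand setting, the annotation and any filter on genes are not given in the sources used here. The values are signal deposited by the authors as size-factor-normalized counts with 1 decimal. The table has 13264 genes, of which 1 is 0 in all libraries, no mitochondrially encoded gene and 95 ribosomal protein genes.

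Within each library at least 99.99% of values were whole multiples of a single step (tolerance 0.05), where at most 25.7% would be by chance, so whole reads were recovered by dividing by that step. A stricter check of the step accepted 50 libraries and left 4 undecided. Recovered reads per library ran from 374982 to 2599349, normalized totals from 869112 to 1051183 and detected genes from 10535 to 12383. Between replicates the chi-square of recovered reads per degree of freedom was 1.50 to 7.25 in 54 pairs (median 2.31), and r of log values was 0.931 to 0.977. Columns were matched to samples by name. The TSC 129S1 columns carry a line number that the labels do not give, and were matched by elimination.

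The 17 comparisons, their test and the rule for naming genes were set before the data were examined. limma 3.58.1 with a mean-variance trend was fitted to log2(value + 1) of all 54 libraries with 1 mean per group, for the 10343 genes with a value of 10 or more in at least 3 libraries. Groups of several lines took the average of the line means. Adjusted p are Benjamini-Hochberg within a comparison, with a threshold of 0.05. The axis position is the projection of a library, minus the ESC mean, on the difference between the means of established TSC and ESC, with ESC and TSC libraries left out of the axis that places them. Pairs of groups were compared by exact permutation, adjusted over 10 pairs. The shared use of ESC libraries gives a position of 0.0251 by itself.

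There were 18 gene lists with 280 genes, set at the same stage: pluripotency, formative, trophoblast stem, shared ESC and TSC, trophoblast differentiation, placental imprinted, primitive endoderm, mesoderm, neural, intestinal, caudal and Hox, YAP/TEAD targets, FGF/ERK response, Wnt response, p53 response, fibroblast, germline genes silenced by methylation and sex chromosome. In the table were 244 of these genes and 213 were tested, and 15 lists had 5 or more tested genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. For the other settings, lists were tested with cameraPR on the gene statistics of each fit, and were compared with cameraPR on the reported fit, whose calls can differ from those of camera. Cdx2 is named in every group. For each comparison up to 4 genes with the greatest absolute difference were eligible from each list of 5 or more tested genes, and beside them the 5 greatest rises and falls among changed genes with no overlap between sides and a mean of 50 or more, without predicted genes. The text names a selection of these.

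The fibroblast level is the median over the fibroblast list of a library's value as a percentage of the MEF mean. Gene positions and exon overlaps come from GENCODE vM21 (GRCm38), which matched 13041 symbols, or 13258 with RefSeq. Of the named genes checked, 9 have exons that overlap another gene, and their counts are uncertain because the counting strand is not given. The same holds for genes with near-identical relatives, such as Rhox6 and Rhox9.

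The test was also tested on simulated data, with 100 genes each changed 2-fold and 4-fold in the LPA comparison at 48 h. limma recovered 75% and 99%, and edgeR 78% and 100%. Of limma's calls 19.1% were unchanged genes, against 3.26% for edgeR, so in this simulation limma's calls held more false ones than the threshold states.

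Other settings chosen beforehand were pseudocounts of 0.5 and 5, no filter, a mean of 50 or more, TMM scaling, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, a fit of only the libraries compared, the replicate number as a block, line means for iTSC against TSC, leaving out each library, and an axis of only changed genes. Added after the data were seen were edgeR on the 50 accepted libraries, a fit without MEF and XEN, the axis of TSC-specific genes, tests without genes over 4-fold higher in MEF than in TSC, and DOX 72 h in place of the samples labelled DOX 48 h. Calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. No library was left out. Transcript isoforms could not be analysed, because the table holds 1 value per gene. Gene length and GC content were not tested.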

Results

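The series measured messenger RNA by bulk MARS-seq, a barcoded method that reads the 3′ ends of transcripts, in mouse cells that pass from embryonic stem cells (ESC) toward trophoblast stem cells (TSC). The starting cells were KH2 ESC, which carry a doxycycline-controlled transactivator at Rosa26, and the iCdx2 cells derived from them hold a Cdx2 transgene at the collagen locus that doxycycline (DOX) switches on. Cdx2 is a homeobox transcription factor of the trophectoderm. Samples of iCdx2 clone 3 were taken after 48, 72 and 96 h and after 5, 6 and 7 days of DOX, and after 4 days of DOX followed by 4 days without it. Others had DOX together with lysophosphatidic acid (LPA), a lipid that the submitters describe as an inhibitor of Hippo signalling, for 48 h, 96 h and 8 days. The labels do not say whether DOX was kept for all 8 days. Derived lines, called iTSC here, were clones 2 and 3 at passage 3. The controls were 3 established TSC lines (BDF2 clone 2, BDF2 clone 5 and 129S1), KH2 ESC in 2i/LIF, embryonic fibroblasts (MEF) and extra-embryonic endoderm (XEN) cells.

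There were 18 groups of 3 libraries, 54 in all. The table listed 13264 genes, and the reads recovered from its size-factor-normalized counts ran from 374982 to 2599349 per library (median 899323). At that depth 1 read was worth between 0.389 and 2.51 normalized counts. Values below are normalized counts, given as mean ± SD over the libraries of a group, and differences are on the log2(value + 1) scale, given ± SE of the limma fit. A gene changed when its adjusted p was below 0.05 among 10343 tested genes. Restricting the tests to the 3656 genes with a mean of 50 or more lowered each of the 17 counts of changed genes by over 1.5 times, because fewer genes were tested. The labels do not say whether the 3 libraries of a group came from separate cultures, so they may be technical replicates.

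Cdx2, on mouse chromosome 5 (GRCm38, the assembly also called mm10, 147300805 to 147307270, minus strand), averaged 2.17 ± 0.586 (SD, n = 3) in ESC. It stood at 1.5 ± 1.67 in the samples labelled DOX 48 h, 57.1 ± 25.3 at 72 h, 41.5 ± 8.06 at 96 h, 65.7 ± 40.6 at 5 d, 101 ± 21.5 at 6 d and 91.9 ± 4.18 at 7 d. After withdrawal of DOX the mean was 24.6 ± 5.29. With LPA the means were 61.7 ± 5.7 at 48 h, 104 ± 5.79 at 96 h and 79.2 ± 3.1 at 8 d. The iTSC clones had 126 ± 9.84 (clone 2) and 94.1 ± 14 (clone 3), and the TSC lines 157 ± 19.7, 108 ± 10 and 210.5 ± 40.2 (BDF2 clone 2, BDF2 clone 5 and 129S1). MEF and XEN had 2.37 ± 2.46 and 0.267 ± 0.462. Whether reads of the transgene are counted as Cdx2 is not given in the sources used here.

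**Figure D1:**
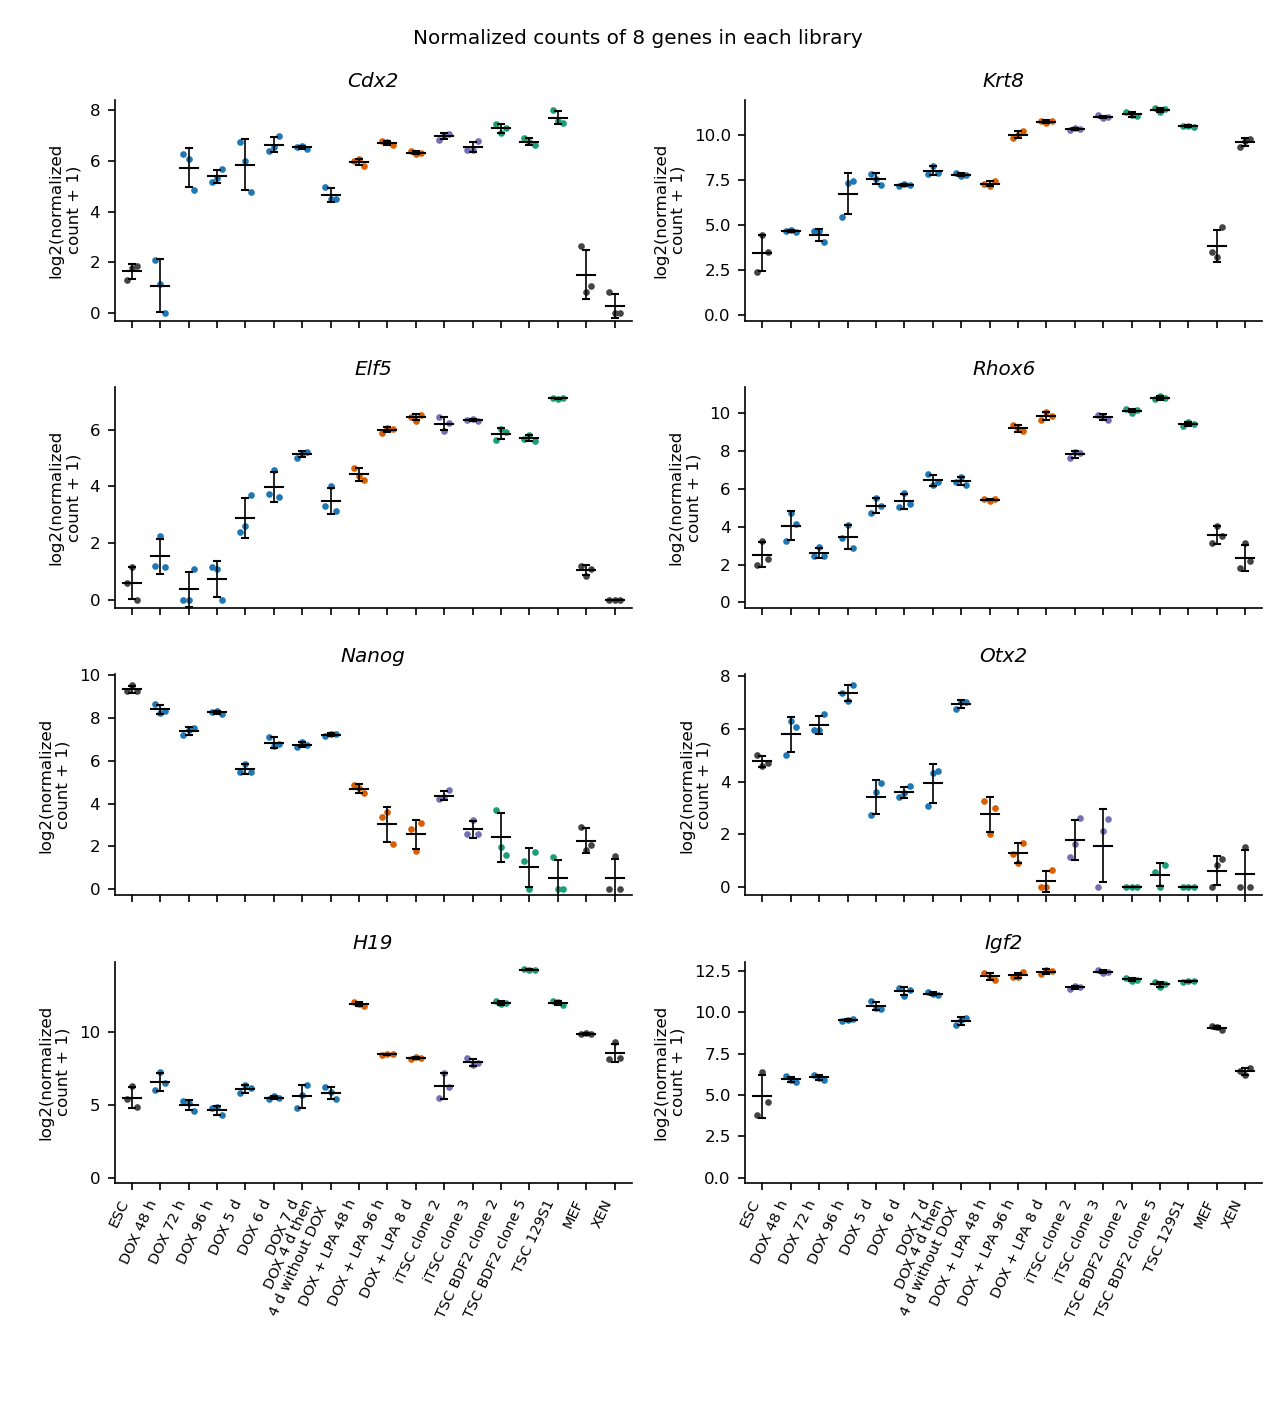
Normalized counts of 8 genes on a log2(value + 1) axis in the 54 libraries by group, where points are libraries and bars the mean ± SD of 3 (blue DOX, orange DOX with LPA, purple iTSC, green established TSC, dark grey ESC, MEF and XEN). Cdx2 averages 1.5 in the samples labelled DOX 48 h and 57.1 at 72 h, and H19 averages 3875 in DOX + LPA 48 h against 356 in DOX + LPA 96 h.

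The end points of the conversion were compared first. Hand1, a transcription factor of trophoblast giant cells, averaged 1118 ± 163 (SD, n = 9) in established TSC and 2.4 ± 2.19 (SD, n = 3) in ESC. The keratins Krt8 (2154 ± 580.2 against 11.9 ± 8.23) and Krt18 (4236 ± 1014 against 24.8 ± 17.1), which form the filaments of simple epithelia, were higher in TSC, as were the X-linked homeobox genes Rhox6 (1215 ± 491 against 5.13 ± 2.97) and Rhox9 (1112 ± 412 against 5.53 ± 2.26). Nanog, a transcription factor of pluripotency, had 2.51 ± 3.76 against 659 ± 77.2, and Tdh, the threonine dehydrogenase on which mouse ESC metabolism depends, 5.38 ± 6.76 against 1627 ± 187. In log2 units (SE, n = 9 and 3) Hand1 rose by 8.66 ± 0.33 and Tdh fell by 8.41 ± 0.38, with adjusted p = 1.7e-29 and 3.3e-26. Cdx2 itself rose by 5.61 ± 0.30.

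Where the median, mean or test of a list differ in sign, all are given. For the trophoblast stem list 21 of 23 tested genes rose, 1 fell and 1 did not pass (21 rose and 1 fell adjusted over the list alone, in parentheses below as list alone, camera adjusted p = 2.3e-12). In the trophoblast differentiation list, which includes the VEGF receptor gene Flt1 (difference 5.97 ± 0.36), 11 of 13 rose, 1 fell and 1 did not pass (list alone 11 and 1, camera adjusted p = 1.5e-05). Among placental imprinted genes 11 of 11 rose, none fell and none did not pass (list alone 11 and none, camera adjusted p = 7.8e-10), led by the untranslated RNA H19 (7.23 ± 0.25), the growth factor gene Igf2 (6.93 ± 0.20), the cell cycle inhibitor gene Cdkn1c (6.19 ± 0.22) and the retrotransposon-derived Peg10 (5.49 ± 0.17). For pluripotency 1 of 20 rose, 18 fell and 1 did not pass (list alone 1 and 18, camera adjusted p = 3.7e-11), with Gdf3 at -7.61 ± 0.37 and Fgf4 at -7.46 ± 0.41. For the genes that ESC and TSC share 1 of 7 rose, 6 fell and none did not pass (list alone 1 and 6, camera adjusted p = 0.019, and adjusted p = 0.18 with an estimated correlation). Lin28a, an RNA-binding regulator, rose by 3.17 ± 0.18, and Klf5 fell by 2.05 ± 0.19.

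Immediate early genes and feedback genes of FGF/ERK signalling were higher in TSC: Fos rose by 6.78 ± 0.23, Egr1 rose by 6.51 ± 0.27 and the phosphatase gene Dusp6 rose by 3.66 ± 0.28. In that list 11 of 13 rose, 2 fell and none did not pass (list alone 11 and 2, camera adjusted p = 5.1e-05). Relative to ESC, which were in 2i/LIF, this list also averaged 1.9 in MEF and 1.86 in XEN. Of the YAP/TEAD targets, among them Axl (4.15 ± 0.27) and Ccn1 (3.98 ± 0.12), 20 of 22 rose, 1 fell and 1 did not pass (list alone 20 and 1, camera adjusted p = 2.0e-08). Wnt response genes included Sp5 (-6.75 ± 0.41) and the Wnt deacylase gene Notum (-2.88 ± 0.32), and 1 of 9 rose, 5 fell and 3 did not pass (list alone 1 and 5, camera adjusted p = 0.057). Fibroblast genes such as S100a4 (5.42 ± 0.22) and Tagln (4.64 ± 0.19) were also higher, and 15 of 18 rose, 1 fell and 2 did not pass (list alone 15 and 1, camera adjusted p = 1.5e-05, and adjusted p = 0.097 with an estimated correlation). The fibroblast level, defined as the median over the fibroblast list of the value as a percentage of the MEF mean, was 3.31% ± 0.715, 6.43% ± 0.0201 and 4.1% ± 0.816 in the TSC lines (BDF2 clone 2, BDF2 clone 5 and 129S1) and 0.809% ± 0.111 in ESC (SD, n = 3). All samples were grown on MEF feeders, per the labels.

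For the formative list, where Pou3f1 rose by 4.91 ± 0.22 and Otx2 fell by 4.61 ± 0.39, 5 of 11 rose, 1 fell and 5 did not pass (list alone 5 and 1, camera adjusted p = 0.098). For primitive endoderm, where the basement membrane collagen genes Col4a1 (4.86 ± 0.12) and Col4a2 (5.23 ± 0.14) stood out and whose exons overlap each other on opposite strands, 10 of 19 rose, 3 fell and 6 did not pass (list alone 10 and 3, camera adjusted p = 0.086). For p53 response 7 of 12 rose, none fell and 5 did not pass (list alone 7 and none, camera adjusted p = 0.066), with Perp at 2.99 ± 0.16 and Mdm2 at 1.39 ± 0.10. For caudal and Hox genes 5 of 17 rose, 3 fell and 9 did not pass (list alone 4 and 3, camera adjusted p = 0.75). For germline genes silenced by methylation 1 of 6 rose, 2 fell and 3 did not pass (list alone 1 and 2, camera adjusted p = 0.16). For mesoderm genes 1 of 5 rose, 1 fell and 3 did not pass (list alone 1 and 1, camera adjusted p = 0.73). Among intestinal genes 1 of 3 rose, 2 fell and none did not pass (list alone 1 and 2, camera adjusted p = 0.68). Among neural genes 1 of 3 rose, none fell and 2 did not pass (list alone 1 and none, camera adjusted p = 0.54). Of the sex chromosome list 1 of 1 rose, none fell and none did not pass (list alone 1 and none, camera adjusted p = 0.47). That gene is Xist, with 19.7 ± 8.38 in TSC BDF2 clone 5 but 0.467 ± 0.503 in BDF2 clone 2, 0.267 ± 0.462 in 129S1 and 0 ± 0 in ESC, so a single line carried the rise.

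In this comparison 6196 of 10343 genes changed, 3233 higher and 2963 lower in TSC, or 3310 and 3505 with edgeR. In 4321 of them, and in 4396 of all tested genes, the 9 TSC libraries did not overlap the 3 ESC libraries. Chance gives this for 0.909% of genes if single libraries are the units. The units here are lines, for which that share is too low. The listed genes that anchor the comparison lie at these GRCm38 positions. Hand1 is on chromosome 11 (57828705 to 57832818), Krt8 and Krt18 on chromosome 15 (101996698 to 102004482 and 102028180 to 102032027), and Rhox6 and Rhox9 on chromosome X (37826910 to 37829857 and 37899097 to 37901770). H19 and Igf2 share an imprinted domain on chromosome 7 (142575529 to 142578143 and 142650766 to 142666816), and Nanog is on chromosome 6 (122707489 to 122714633). Rhox6 and Rhox9 are close relatives, and the sources used here do not give how reads shared between related genes were counted.

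Each library was then placed on a line from the ESC mean (0) to the mean of established TSC (1) over all tested genes. Positions were 0.298 ± 0.0177 (SD, n = 3) in the samples labelled DOX 48 h, 0.372 ± 0.029 at DOX 96 h, 0.607 ± 0.0186 at 5 d, 0.565 ± 0.0167 at 6 d and 0.61 ± 0.00915 at 7 d, with 0.562 ± 0.0114 after withdrawal. LPA groups lay at 0.557 ± 0.00507 (48 h), 0.775 ± 0.00963 (96 h) and 0.947 ± 0.00368 (8 d), and the iTSC clones at 0.838 ± 0.00207 (clone 2) and 0.962 ± 0.0158 (clone 3). MEF (0.983 ± 0.0239) and XEN (0.819 ± 0.0299) also lay far along this line, so it measures distance from ESC as much as likeness to TSC. A line restricted to 409 genes higher in established TSC than in ESC, MEF and XEN put DOX 5 d at 0.475 ± 0.00674, DOX 6 d at 0.525 ± 0.0131, DOX 7 d at 0.612 ± 0.00324, DOX + LPA 8 d at 0.929 ± 0.0133 and the iTSC clones at 0.742 ± 0.0197 and 0.864 ± 0.0181 (clones 2 and 3). Its genes passed against each of those groups in limma at adjusted p below 0.05, with a log2 difference above 1. This line was chosen after the data were seen, and its genes were picked for low levels in MEF and XEN, so it says nothing on where MEF and XEN lie. In exact permutation tests of 10 pairs of groups, 9 pairs including each LPA group against its control had no overlap and p = 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.111). Over all tested genes DOX 7 d and DOX 5 d differed by 0.00262 (exact p = 0.90), while on the line of TSC-specific genes DOX 7 d lay above DOX 5 d.

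**Figure D2:**
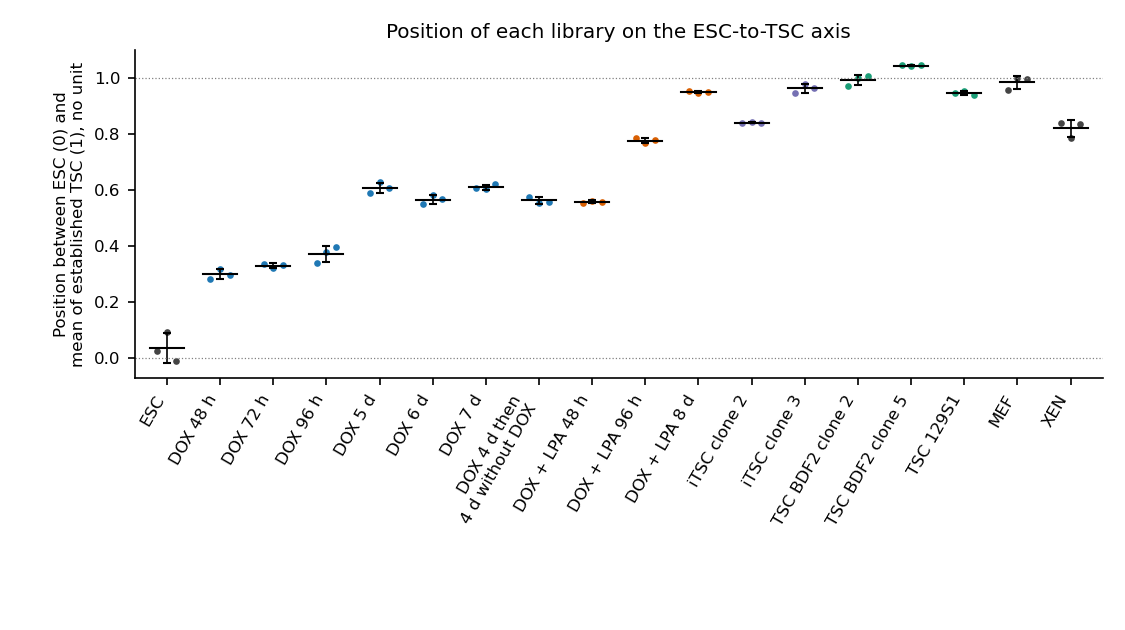
Position of each of the 54 libraries between the ESC mean (0) and the mean of established TSC (1), with no unit, where points are libraries and bars the mean ± SD of 3 (blue DOX, orange DOX with LPA, purple iTSC, green established TSC, dark grey ESC, MEF and XEN). DOX + LPA 8 d averages 0.947 and DOX 7 d 0.61.

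The DOX series asks what changes while Cdx2 is induced. In the samples labelled DOX 48 h, the DNA methyltransferase cofactor gene Dnmt3l, whose exons overlap Aire on the other strand, averaged 755 ± 93.9 (SD, n = 3) against 9.8 ± 2.78 in ESC. Among FGF/ERK genes, Egr1 rose by 6.06 ± 0.33 and the feedback inhibitor gene Spry4 rose by 5.49 ± 0.28 (SE, n = 3 and 3), and 10 of 13 rose, none fell and 3 did not pass (list alone 11 and none, camera adjusted p = 2.3e-12). In the formative list, where the de novo methyltransferase gene Dnmt3b rose by 3.3 ± 0.21, 7 of 11 rose, none fell and 4 did not pass (list alone 7 and none, camera adjusted p = 9.6e-07). For pluripotency, where Utf1 rose by 4.12 ± 0.27 and Tfcp2l1 fell by 2.1 ± 0.28, 5 of 20 rose, 3 fell and 12 did not pass (list alone 6 and 5, camera adjusted p = 0.92, median -0.04, mean 0.05, test down). The water channel gene Aqp3 fell by 5.68 ± 0.55. Cdx2 did not pass, at -0.56 ± 0.36 (adjusted p = 0.27).

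Of the trophoblast stem list 9 of 23 rose, 5 fell and 9 did not pass (list alone 9 and 5, camera adjusted p = 0.84). Of the caudal and Hox list 1 of 17 rose, 6 fell and 10 did not pass (list alone 1 and 7, camera adjusted p = 0.055), with Hoxd9 at 0.40 ± 0.693 against 15.4 ± 1.8 and Cdx1 at 24.2 ± 11.4 against 131 ± 7.9. For YAP/TEAD targets, such as Gadd45a (2.62 ± 0.18), 15 of 22 rose, 1 fell and 6 did not pass (list alone 15 and 1, camera adjusted p = 9.6e-07). In the placental imprinted list, where Phlda2 rose by 3.81 ± 0.28 and Mest fell by 3.51 ± 0.53, 7 of 11 rose, 2 fell and 2 did not pass (list alone 7 and 2, camera adjusted p = 2.7e-04). Fibroblast genes, where the level was 2.41% ± 0.0347 of MEF, gave this count: 11 of 18 rose, 1 fell and 6 did not pass (list alone 12 and 1, camera adjusted p = 9.6e-07, and adjusted p = 0.069 with an estimated correlation). In all 2842 genes changed (1555 higher, 1287 lower), 2672 of them with no overlap between the libraries. Of all 10343 tested genes 4323 had no overlap, which chance gives for 10% of genes with 3 against 3. The ESC were in 2i/LIF and the series has no uninduced iCdx2 library, so this comparison and those of later DOX times with ESC also differ in line and culture.

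At 72 h of DOX, the MAPK phosphatase gene Dusp4 averaged 337 ± 26.9 against 2.63 ± 1.22 in ESC (SD, n = 3 and 3), and Spry4 214 ± 6.97 against 1.87 ± 2.21. Lefty1, which encodes an inhibitor of Nodal signalling, rose by 5.28 ± 0.33, and Cdx2 rose by 4.1 ± 0.36 (SE, n = 3 and 3). Posterior Hox genes were among those that rose: Hoxb8 by 4.01 ± 0.55 and Hoxb7 by 3.0 ± 0.46. In the caudal and Hox list 8 of 17 rose, 2 fell and 7 did not pass (list alone 8 and 2, camera adjusted p = 0.098). Prdm14 fell by 4.64 ± 0.47 and Nanog fell by 1.97 ± 0.42. For pluripotency 4 of 20 rose, 6 fell and 10 did not pass (list alone 4 and 7, camera adjusted p = 0.20). Among trophoblast stem genes 10 of 23 rose, 5 fell and 8 did not pass (list alone 10 and 7, camera adjusted p = 0.67), with Cdh3 at 2.71 ± 0.42. Wnt response genes Sp5 (-5.74 ± 0.50) and Notum (-3.23 ± 0.39) were lower, and 1 of 9 rose, 5 fell and 3 did not pass (list alone 1 and 5, camera adjusted p = 0.0098, and adjusted p = 0.081 with an estimated correlation). In the p53 response list, where Cdkn1a fell by 1.97 ± 0.17, 2 of 12 rose, 5 fell and 5 did not pass (list alone 2 and 5, camera adjusted p = 0.039, and adjusted p = 0.14 with an estimated correlation). Changed genes numbered 3413 (1914 higher, 1499 lower).

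At 96 h the imprinted genes Peg10 (409.6 ± 34.1 against 13.8 ± 6.21 in ESC, SD, n = 3 and 3) and Igf2 (736 ± 22 against 38.9 ± 36.9) were higher. In their list 7 of 11 rose, 2 fell and 2 did not pass (list alone 8 and 2, camera adjusted p = 1.6e-05). Id2, an inhibitor of basic helix-loop-helix factors, rose by 4.78 ± 0.23 and Krt18 rose by 3.55 ± 0.27 (SE, n = 3 and 3). Of trophoblast stem genes 14 of 23 rose, 4 fell and 5 did not pass (list alone 14 and 4, camera adjusted p = 1.8e-04). Cdx2 rose by 3.75 ± 0.36. Of trophoblast differentiation genes 8 of 13 rose, 1 fell and 4 did not pass (list alone 8 and 1, camera adjusted p = 0.0032), with Ascl2 at 3.06 ± 0.39 and Cited1 at 2.33 ± 0.25. Otx2 (2.58 ± 0.48) and Cldn6 (3.88 ± 0.20) belong to the formative list, in which 8 of 11 rose, none fell and 3 did not pass (list alone 9 and none, camera adjusted p = 3.6e-05). Of the caudal and Hox genes 8 of 17 rose, 2 fell and 7 did not pass (list alone 9 and 2, camera adjusted p = 0.048, and adjusted p = 0.073 with an estimated correlation). The collagen genes Col1a1 (-3.58 ± 0.31) and Col3a1 (-3.29 ± 0.27) were lower than in ESC, and in the fibroblast list, at a level of 0.72% ± 0.252 of MEF, 4 of 18 rose, 6 fell and 8 did not pass (list alone 5 and 6, camera adjusted p = 0.90). There were 3525 changed genes (1867 higher, 1658 lower).

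At 5 d, markers of fibroblasts were higher beside the trophoblast genes, but the lists took different courses. Relative to ESC the fibroblast list averaged -0.149 at 96 h, 3.23 at 5 d, 2.18 at 6 d and 1.1 at 7 d. At the same times the trophoblast stem list averaged 1.23, 1.86, 2.14 and 2.6. The YAP/TEAD targets averaged 1.19, 2.435, 2.13 and 1.825, and 3.81 in MEF. S100a4 averaged 319.5 ± 77.3 against 1.8 ± 1.14 in ESC (SD, n = 3 and 3) and Tagln 539 ± 18.5 against 12.2 ± 9.04, and the fibroblast level was 11% ± 0.71 of MEF. In that list 17 of 18 rose, none fell and 1 did not pass (list alone 17 and none, camera adjusted p = 3.3e-14). Wnt7b rose by 4.97 ± 0.39, Id2 rose by 5.08 ± 0.23 and Krt8 rose by 4.1 ± 0.31 (SE, n = 3 and 3), and Cdx2 rose by 4.2 ± 0.36. For the trophoblast stem list 16 of 23 rose, 3 fell and 4 did not pass (list alone 16 and 3, camera adjusted p = 2.0e-06). Among YAP/TEAD targets, with Axl at 5.27 ± 0.33 and Ankrd1 at 4.12 ± 0.42, 19 of 22 rose, none fell and 3 did not pass (list alone 19 and none, camera adjusted p = 5.2e-13). Hoxb8 (3.98 ± 0.55) and Hoxa9 (2.86 ± 0.50) were higher. In the caudal and Hox list 13 of 17 rose, 1 fell and 3 did not pass (list alone 13 and 1, camera adjusted p = 0.0021). That list lost its call and its camera direction turned (mean 0.01) when genes over 4-fold higher in MEF than in TSC were left out, a setting chosen after the data were seen. Nanog fell by 3.76 ± 0.42 and Tcl1 fell by 4.72 ± 0.56. For pluripotency 3 of 20 rose, 13 fell and 4 did not pass (list alone 4 and 14, camera adjusted p = 9.3e-05). The matrix gene Mgp rose by 5.84 ± 0.26. In total 4160 genes changed (2357 higher, 1803 lower).

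At 6 d the largest rises included Igf2 (2486 ± 418 against 38.9 ± 36.9 in ESC, SD, n = 3 and 3), Peg10 (1076 ± 204 against 13.8 ± 6.21) and the Wnt ligand gene Wnt7b (203 ± 33.4 against 2.67 ± 3.12). Cdx2 rose by 5.0 ± 0.36, Bmp4 rose by 4.35 ± 0.28 and Hand1 rose by 4.88 ± 0.40 (SE, n = 3 and 3). Among trophoblast stem genes 17 of 23 rose, 3 fell and 3 did not pass (list alone 17 and 3, camera adjusted p = 2.7e-08). Among placental imprinted genes 8 of 11 rose, 1 fell and 2 did not pass (list alone 8 and 1, camera adjusted p = 4.0e-08). Pluripotency genes included Prdm14 (-4.22 ± 0.47) and Tdh (-3.36 ± 0.46), and 2 of 20 rose, 14 fell and 4 did not pass (list alone 3 and 14, camera adjusted p = 2.4e-05). For caudal and Hox genes 13 of 17 rose, 1 fell and 3 did not pass (list alone 13 and 1, camera adjusted p = 0.0014), and for the fibroblast list, at a level of 4.27% ± 0.625 of MEF, 15 of 18 rose, none fell and 3 did not pass (list alone 15 and none, camera adjusted p = 1.1e-08). Changes numbered 3812 (2172 higher, 1640 lower).

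At 7 d of DOX, Wnt7b averaged 316 ± 37 (SD, n = 3) against 2.67 ± 3.12 in ESC, Igf2 2232 ± 158 against 38.9 ± 36.9 and Krt18 593 ± 63.8 against 24.8 ± 17.1. Wnt7b rose by 6.85 ± 0.39, Id2 rose by 5.31 ± 0.23 and Cdx2 rose by 4.89 ± 0.36 (SE, n = 3 and 3, adjusted p = 1.4e-16 for Cdx2). Of trophoblast stem genes 19 of 23 rose, 2 fell and 2 did not pass (list alone 19 and 2, camera adjusted p = 2.3e-10). Hand1 rose by 5.13 ± 0.40 and the transcriptional coregulator gene Cited1 rose by 3.89 ± 0.25. Among trophoblast differentiation genes 7 of 13 rose, 1 fell and 5 did not pass (list alone 8 and 1, camera adjusted p = 0.0038). Peg10 rose by 5.15 ± 0.21 and the maternally expressed Phlda2 rose by 3.5 ± 0.28. Of placental imprinted genes 8 of 11 rose, 1 fell and 2 did not pass (list alone 9 and 1, camera adjusted p = 6.0e-08). Klf4 fell by 3.26 ± 0.21, Tdh fell by 3.78 ± 0.46 and Tcl1 fell by 4.41 ± 0.56. Of pluripotency genes 1 of 20 rose, 14 fell and 5 did not pass (list alone 2 and 15, camera adjusted p = 5.9e-07).

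Signalling lists also differed at 7 d from ESC, whose line and culture (2i/LIF) differ too. Egr1 rose by 6.15 ± 0.33, Fos rose by 5.31 ± 0.28 and Dusp6 rose by 5.03 ± 0.35. For FGF/ERK response 11 of 13 rose, 1 fell and 1 did not pass (list alone 11 and 1, camera adjusted p = 4.3e-10). Sp5 fell by 5.63 ± 0.50, Notum fell by 4.75 ± 0.39 and Axin2 fell by 2.38 ± 0.44. For Wnt response none of 9 rose, 5 fell and 4 did not pass (list alone none and 5, camera adjusted p = 0.0041). YAP/TEAD targets included F3 (3.7 ± 0.20) and Ccn1 (3.03 ± 0.14). There 17 of 22 rose, 1 fell and 4 did not pass (list alone 17 and 1, camera adjusted p = 1.7e-09). In the formative list, with Cldn6 at 4.66 ± 0.20 and Dnmt3b at 3.49 ± 0.21, 8 of 11 rose, none fell and 3 did not pass (list alone 9 and none, camera adjusted p = 7.7e-05). In the caudal and Hox list, with Hoxb8 at 3.2 ± 0.55 and Cdx1 at -3.12 ± 0.41, 11 of 17 rose, 2 fell and 4 did not pass (list alone 12 and 2, camera adjusted p = 0.0051). Without genes over 4-fold higher in MEF than in TSC, again a later choice that took out members of the list, that list lost its call and its camera direction turned (mean 0.18). For fibroblast genes, at a level of 2.19% ± 0.204 of MEF, 10 of 18 rose, 2 fell and 6 did not pass (list alone 10 and 2, camera adjusted p = 0.0038, and adjusted p = 0.24 with an estimated correlation). The p53 response list held Perp (3.12 ± 0.20) and Cdkn1a (-2.04 ± 0.17). There 2 of 12 rose, 4 fell and 6 did not pass (list alone 2 and 4, camera adjusted p = 0.60). Changed genes came to 4188 (2276 higher, 1912 lower), and 3908 of them had no overlap between libraries. Of all tested genes 5154 had no overlap (chance share 10%).

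A comparison within the DOX series avoids the ESC control. Between the samples labelled DOX 48 h and those at 7 d, Cited1 moved from 10.8 ± 7.06 to 722 ± 14.2 (SD, n = 3 and 3), Eomes, a T-box factor of TSC, from 6.4 ± 4.85 to 109 ± 8.49, and Igf2 from 60.7 ± 7.29 to 2232 ± 158. Cdx2 rose by 5.46 ± 0.36, Wnt7b rose by 5.46 ± 0.39 and the secretin gene Sct rose by 5.93 ± 0.50 (SE, n = 3 and 3). For the trophoblast stem list 19 of 23 rose, none fell and 4 did not pass (list alone 19 and none, camera adjusted p = 6.8e-21). Hoxd9 rose by 4.65 ± 0.57 and Hoxc9 rose by 4.01 ± 0.48. Of the caudal and Hox genes 13 of 17 rose, none fell and 4 did not pass (list alone 14 and none, camera adjusted p = 6.8e-09). Klf4 fell by 2.93 ± 0.21 and Tdh fell by 3.12 ± 0.46. For pluripotency none of 20 rose, 18 fell and 2 did not pass (list alone none and 19, camera adjusted p = 1.6e-12). Peg3 rose by 2.99 ± 0.37. Of placental imprinted genes 8 of 11 rose, 1 fell and 2 did not pass (list alone 8 and 1, camera adjusted p = 8.7e-06). Notum fell by 3.58 ± 0.39 and Lef1 fell by 2.49 ± 0.50. For Wnt response 1 of 9 rose, 4 fell and 4 did not pass (list alone 1 and 4, camera adjusted p = 0.030, and adjusted p = 0.11 with an estimated correlation). The count was 2551 (1364 higher, 1187 lower). With DOX 72 h in place of the samples labelled DOX 48 h, chosen after the data were seen, Dusp4 went from 3.02 ± 0.23 to -1.59 and passed, while Sp5 (from -1.77 ± 0.50 to 0.10), Cdx2 (0.79), Hoxd9 (0.86) and Lef1 (-0.83) no longer passed. The caudal and Hox list (mean 0.50) and the Wnt response list (-0.31) lost their calls with that control, and the p53 response list (0.38) gained one.

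The samples with 4 days of DOX and 4 days without it show what follows withdrawal. Against DOX 96 h, Hand1 averaged 119 ± 31 against 1.97 ± 1.1 (SD, n = 3 and 3), Sox3, a SoxB1 factor, 97.1 ± 14.7 against 4.5 ± 2.7 and Pou3f1 259 ± 28.2 against 24 ± 11, while the acute phase gene Saa3 had 2.6 ± 1.38 against 224 ± 73.3. In the formative list 8 of 11 rose, none fell and 3 did not pass (list alone 9 and none, camera adjusted p = 1.6e-06). Cubn (4.03 ± 0.49) and Amn (3.29 ± 0.49, SE, n = 3 and 3) rose. Of primitive endoderm genes 15 of 19 rose, 1 fell and 3 did not pass (list alone 15 and 1, camera adjusted p = 2.6e-11). Hoxd9 fell by 3.34 ± 0.57 and Hoxc9 fell by 3.14 ± 0.48. In the caudal and Hox list none of 17 rose, 10 fell and 7 did not pass (list alone 1 and 10, camera adjusted p = 2.2e-06). Klf4 fell by 3.06 ± 0.21 and Tbx3 fell by 2.62 ± 0.24. For pluripotency 1 of 20 rose, 12 fell and 7 did not pass (list alone 1 and 13, camera adjusted p = 7.6e-07). In the trophoblast stem list, where Rhox9 rose by 2.99 ± 0.27 and Id2 fell by 1.89 ± 0.23, 7 of 23 rose, 4 fell and 12 did not pass (list alone 8 and 4, camera adjusted p = 0.28). Cdx2 did not pass, at -0.73 ± 0.36 (adjusted p = 0.15). In the fibroblast list, at a level of 2.52% ± 0.48 of MEF against 0.72% ± 0.252, 13 of 18 rose, none fell and 5 did not pass (list alone 14 and none, camera adjusted p = 2.1e-09). The changed genes numbered 2408 (1436 higher, 972 lower). The share that was higher moved by up to 7.49 percentage points under other preset settings.

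Against 7 d of continued DOX, a total time that differs by a day, Cdx2 averaged 24.6 ± 5.29 against 91.9 ± 4.18 (SD, n = 3 and 3) and fell by 1.88 ± 0.36 (SE, n = 3 and 3, adjusted p = 1.8e-04). Wnt7b fell by 2.6 ± 0.39 and Id2 fell by 2.42 ± 0.23. Among trophoblast stem genes none of 23 rose, 10 fell and 13 did not pass (list alone none and 12, camera adjusted p = 1.5e-08). Hoxd9 fell by 3.5 ± 0.57 and Hoxb9 fell by 3.32 ± 0.54. For caudal and Hox genes none of 17 rose, 12 fell and 5 did not pass (list alone none and 14, camera adjusted p = 2.5e-13). Otx2 rose by 2.99 ± 0.48, Fgf15 rose by 2.7 ± 0.48 and Fgf8 rose by 3.58 ± 0.59. For the formative list 8 of 11 rose, none fell and 3 did not pass (list alone 8 and none, camera adjusted p = 1.9e-07). Cubn rose by 3.43 ± 0.49, Foxq1 rose by 3.13 ± 0.52 and Gata4 rose by 1.93 ± 0.43. For primitive endoderm 10 of 19 rose, none fell and 9 did not pass (list alone 16 and none, camera adjusted p = 2.9e-12). Igf2 fell by 1.66 ± 0.25. Of placental imprinted genes 1 of 11 rose, 3 fell and 7 did not pass (list alone 1 and 6, camera adjusted p = 0.019, and adjusted p = 0.16 with an estimated correlation). Tdgf1 rose by 1.98 ± 0.50. For pluripotency 5 of 20 rose, 1 fell and 14 did not pass (list alone 9 and 1, camera adjusted p = 0.14). In all 1268 genes changed (671 higher, 597 lower). Under TMM scaling 562 were higher and 734 lower, and without the library of replicate 3 of the withdrawal group 445 and 464, so the side with more genes depends on the setting. Fitting only these 6 libraries lowered the count to 627.

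The iTSC clones were compared with ESC to ask what the derived lines had become. Krt8 averaged 1692 ± 425 against 11.9 ± 8.23 (SD, n = 6 and 3), Hand1 667 ± 441 against 2.4 ± 2.19 and Wnt7b 393 ± 71.8 against 2.67 ± 3.12. Krt8 rose by 7.22 ± 0.27, Rhox6 rose by 6.3 ± 0.25 and Cdx2 rose by 5.13 ± 0.32 (SE, n = 6 and 3). Of trophoblast stem genes 19 of 23 rose, 1 fell and 3 did not pass (list alone 20 and 1, camera adjusted p = 9.3e-12). Hand1 rose by 7.61 ± 0.35, Cebpa rose by 4.43 ± 0.39 and Flt1 rose by 4.33 ± 0.39. Of trophoblast differentiation genes 10 of 13 rose, 1 fell and 2 did not pass (list alone 10 and 1, camera adjusted p = 2.2e-05). Tcl1 fell by 7.55 ± 0.48, Tdh fell by 7.42 ± 0.40 and Fgf4 fell by 5.8 ± 0.44. For pluripotency 1 of 20 rose, 18 fell and 1 did not pass (list alone 1 and 18, camera adjusted p = 9.2e-11). Igf2 rose by 7.06 ± 0.21. Of placental imprinted genes 10 of 11 rose, 1 fell and none did not pass (list alone 10 and 1, camera adjusted p = 1.0e-06). Axl rose by 5.57 ± 0.28 and Ccn1 rose by 4.29 ± 0.13. For YAP/TEAD targets 20 of 22 rose, none fell and 2 did not pass (list alone 20 and none, camera adjusted p = 9.2e-11). S100a4 rose by 7.08 ± 0.24, and the fibroblast level was 7.33% ± 0.754 (clone 2) and 13.2% ± 1.51 (clone 3) of MEF. For the fibroblast list 16 of 18 rose, none fell and 2 did not pass (list alone 16 and none, camera adjusted p = 4.0e-10). Fos rose by 5.76 ± 0.25. For FGF/ERK response 11 of 13 rose, 2 fell and none did not pass (list alone 11 and 2, camera adjusted p = 2.9e-06), a list that was also higher than ESC in MEF and XEN. The changed genes were 5851 (3001 higher, 2850 lower), or 2877 higher and 2998 lower under TMM scaling.

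Set against established TSC, the iTSC clones show how these lines differ. H19 averaged 167 ± 96.7 (SD, n = 6) in iTSC and 9328 ± 7838 (SD, n = 9) in established TSC, and the imprinted Mest 4.35 ± 1.87 against 122 ± 26.5. Among the TSC lines, BDF2 clone 5 had by far the highest H19 level. The interferon-induced genes Isg15 (12.7 ± 10.5 against 346 ± 228) and Ifi27 (11.9 ± 8.33 against 142 ± 77) and the liver-type glycogen phosphorylase gene Pygl (6.05 ± 1.67 against 121 ± 75.5) were also lower in iTSC. S100a4 had 364 ± 68.9 against 126 ± 67.6, the fibronectin gene Fn1 1653 ± 611 against 614 ± 332 and Bex4 134 ± 88.8 against 22.3 ± 4.2. Bex4 averaged 214 ± 18.9 in clone 2 and 53.6 ± 6.89 in clone 3. In log2 units (SE, n = 6 and 9) H19 fell by 5.64 ± 0.19, Isg15 fell by 4.58 ± 0.39, Bex4 rose by 2.23 ± 0.17 and Actg2, a smooth muscle actin gene, rose by 1.87 ± 0.26.

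Placental imprinted genes gave this count: none of 11 rose, 5 fell and 6 did not pass (list alone none and 6, camera adjusted p = 1.3e-04), with Cdkn1c at -1.38 ± 0.17 and Meg3 at -0.97 ± 0.14. Cdkn1c averaged 111 ± 22.8 in clone 2 and 461 ± 27.2 in clone 3. Meg3 averaged 92.5 ± 8.79 in clone 2 and 25.9 ± 1.87 in clone 3, so different clones carried most of these falls. In the trophoblast stem list, where Rhox9 fell by 1.72 ± 0.17, Gata3 fell by 1.5 ± 0.22 and Rhox6 fell by 1.33 ± 0.18, 2 of 23 rose, 11 fell and 10 did not pass (list alone 3 and 12, camera adjusted p = 0.016, and adjusted p = 0.11 with an estimated correlation). Cdx2 did not pass, at -0.49 ± 0.24 (adjusted p = 0.11). Among trophoblast differentiation genes 3 of 13 rose, 6 fell and 4 did not pass (list alone 3 and 6, camera adjusted p = 0.30), with Plac1 at -1.66 ± 0.28 and Flt1 at -1.64 ± 0.29. Tdgf1 had 57.6 ± 42.4 against 3.3 ± 3.51 and Nanog 13 ± 7.9 against 2.51 ± 3.76, and clone 2 carried most of this, with Tdgf1 at 95.5 ± 12.9 in clone 2 and 19.7 ± 5.2 in clone 3. In that list 8 of 20 rose, 2 fell and 10 did not pass (list alone 10 and 2, camera adjusted p = 0.023, and adjusted p = 0.31 with an estimated correlation). Hoxa7 rose by 1.62 ± 0.31 and Hoxb7 rose by 1.23 ± 0.30. Of caudal and Hox genes 7 of 17 rose, none fell and 10 did not pass (list alone 9 and 1, camera adjusted p = 0.016). Axl rose by 1.42 ± 0.21. For YAP/TEAD targets 8 of 22 rose, 1 fell and 13 did not pass (list alone 8 and 1, camera adjusted p = 0.016, and adjusted p = 0.19 with an estimated correlation). Fos fell by 1.02 ± 0.18 and Spry4 rose by 1.02 ± 0.18. For FGF/ERK response 6 of 13 rose, 2 fell and 5 did not pass (list alone 8 and 2, camera adjusted p = 0.089). Notum fell by 1.7 ± 0.25 and Axin2 fell by 1.13 ± 0.29. For Wnt response 2 of 9 rose, 5 fell and 2 did not pass (list alone 3 and 5, camera adjusted p = 0.30). Fn1 rose by 1.52 ± 0.11 and Tagln rose by 1.44 ± 0.15. For fibroblast genes 13 of 18 rose, none fell and 5 did not pass (list alone 15 and none, camera adjusted p = 3.4e-10), at the levels of MEF given above. The mean of clone 3 lay within the range of the TSC lines for 11 of 18 lists and that of clone 2 for 6. How many lists of a further established line would lie within that range was not tested, so these counts have no baseline. Relative to ESC the pluripotency list averaged -2.99 in clone 2, -4.17 in clone 3 and -3.98, -4.55 and -4.18 in the TSC lines. The trophoblast stem list averaged 3.35 in clone 2, 4.0 in clone 3 and 3.95, 4.08 and 4.17 in the TSC lines, and Rhox9 124 ± 8.54 in clone 2 and 803 ± 51.7 in clone 3. Lists for which both clones lay outside the range included placental imprinted genes (2.64 and 3.06, against 3.58 to 4.55). They also included fibroblast genes (2.71 and 3.44, against 1.56 to 2.68), where clone 2 lay only just outside. These lists are examples and were not tested as particular to iTSC.

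Of all tested genes 405 had no overlap between the 6 and 9 libraries, against a chance share of 0.040% that takes libraries, not lines, as units. The changed genes came to 3230 (1562 higher, 1668 lower), 400 of them among these. Under TMM scaling 1341 were higher and 1933 lower, but 882 and 686 among genes with a mean of 50 or more, and 1633 and 1529 with edgeR, so the larger side depends on the setting. That test takes libraries of a line as replicates of the comparison. With the means of the 2 clones and 3 lines as the values, limma called 1 gene, Mest, which was lower in iTSC, so the result describes these lines and not derived and established TSC in general.

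The iTSC clones also differed from each other. Rhox9 averaged 803 ± 51.7 against 124 ± 8.54 in clone 2 (SD, n = 3 and 3), the transglutaminase gene Tgm2 285 ± 35.1 against 39.5 ± 8.57 and Hand1 1065 ± 100.3 against 269 ± 17.7. Rhox6 rose by 1.95 ± 0.28 and Gata2 rose by 1.67 ± 0.32 (SE, n = 3 and 3). For the trophoblast stem list 7 of 23 rose, 1 fell and 15 did not pass (list alone 8 and 1, camera adjusted p = 8.8e-04). Of trophoblast differentiation genes, with Plac1 at 1.92 ± 0.43, 6 of 13 rose, none fell and 7 did not pass (list alone 7 and 2, camera adjusted p = 0.0064). Dppa5a fell by 3.87 ± 0.48, Tdgf1 fell by 2.25 ± 0.50 and Fgf4 fell by 3.1 ± 0.50. For pluripotency 1 of 20 rose, 10 fell and 9 did not pass (list alone 1 and 11, camera adjusted p = 2.3e-04, and adjusted p = 0.14 with an estimated correlation). Cdkn1c rose by 2.06 ± 0.27, H19 rose by 1.63 ± 0.30 and Meg3 fell by 1.8 ± 0.22. Of placental imprinted genes 4 of 11 rose, 1 fell and 6 did not pass (list alone 6 and 1, camera adjusted p = 0.14). Thy1 rose by 1.49 ± 0.23 and Col1a1 rose by 1.37 ± 0.31, the fibroblast level being 13.2% ± 1.51 of MEF in clone 3 and 7.33% ± 0.754 in clone 2. In that list 7 of 18 rose, none fell and 11 did not pass (list alone 9 and none, camera adjusted p = 2.6e-04, and adjusted p = 0.20 with an estimated correlation). Cdx2 did not pass, at -0.42 ± 0.36 (adjusted p = 0.44). Changed genes numbered 2370 (1154 higher, 1216 lower), or 1450 when only these 6 libraries were fitted, where H19 (1.63) no longer passed. In that fit 858 were higher and 592 lower, and under TMM scaling 978 and 1396, so which side held more genes depends on the setting.

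The LPA groups ask what LPA adds to Cdx2 induction. Inhibition of Hippo signalling by LPA is the description of the submitters and was not measured here. At 48 h, DOX with LPA was set against the samples labelled DOX 48 h. Igf2 averaged 4584 ± 691 against 60.7 ± 7.29 without LPA (SD, n = 3 and 3), H19 3875 ± 424 against 102 ± 43.9, Sct 1122 ± 77 against 6.63 ± 6.86 and Cited1 1531 ± 228 against 10.8 ± 7.06. Cdx2 differed as well, at 61.7 ± 5.7 against 1.5 ± 1.67, so the libraries compared differ in Cdx2 as well as in LPA. Sct rose by 7.89 ± 0.50, Cited1 rose by 7.17 ± 0.25, Igf2 rose by 6.21 ± 0.25, H19 rose by 5.32 ± 0.30 and Cdx2 rose by 4.88 ± 0.36 (SE, n = 3 and 3). Tdgf1 fell by 5.6 ± 0.50, Fgf4 fell by 5.23 ± 0.50, Tdh fell by 4.85 ± 0.46 and the hormone gene Trh fell by 5.45 ± 0.50.

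In the trophoblast stem list, with Id2 at 5.04 ± 0.23, Gata3 at 4.06 ± 0.34 and Rhox9 at 3.6 ± 0.27, 18 of 23 rose, 1 fell and 4 did not pass (list alone 18 and 1, camera adjusted p = 1.9e-11). Among trophoblast differentiation genes, with Hand1 at 3.14 ± 0.40 and Gjb3 at 2.69 ± 0.19, 7 of 13 rose, 2 fell and 4 did not pass (list alone 7 and 2, camera adjusted p = 0.0026). Placental imprinted genes gave this count: 8 of 11 rose, 2 fell and 1 did not pass (list alone 8 and 2, camera adjusted p = 8.7e-06), with Mest at 4.29 ± 0.53 and Peg3 at 3.62 ± 0.37. For pluripotency 2 of 20 rose, 18 fell and none did not pass (list alone 2 and 18, camera adjusted p = 1.2e-09). Hoxd9 rose by 3.88 ± 0.57 and Hoxa7 rose by 3.19 ± 0.47. Of the caudal and Hox genes 13 of 17 rose, none fell and 4 did not pass (list alone 14 and none, camera adjusted p = 9.4e-06). The tissue factor gene F3 rose by 3.47 ± 0.20, Ptpn14 rose by 2.49 ± 0.25 and Amotl2 rose by 1.74 ± 0.17. For YAP/TEAD targets 11 of 22 rose, 3 fell and 8 did not pass (list alone 11 and 4, camera adjusted p = 0.0076, and adjusted p = 0.13 with an estimated correlation). Otx2 fell by 3.02 ± 0.48 and Sox3 fell by 3.42 ± 0.48. For the formative list 1 of 11 rose, 5 fell and 5 did not pass (list alone 1 and 6, camera adjusted p = 0.022, and adjusted p = 0.11 with an estimated correlation). That list lost its call, and its mean turned to 0.46 among genes with a mean of 50 or more. Notum fell by 3.26 ± 0.39 and Axin2 fell by 1.84 ± 0.44. For Wnt response none of 9 rose, 5 fell and 4 did not pass (list alone none and 5, camera adjusted p = 0.0076, and adjusted p = 0.057 with an estimated correlation). Dusp4 rose by 4.33 ± 0.23 and Etv5 fell by 1.5 ± 0.18. For FGF/ERK response 3 of 13 rose, 3 fell and 7 did not pass (list alone 3 and 3, camera adjusted p = 0.79). Perp rose by 2.06 ± 0.20 and Mdm2 rose by 1.36 ± 0.13. For p53 response 4 of 12 rose, 1 fell and 7 did not pass (list alone 4 and 1, camera adjusted p = 0.47, median -0.16, mean 0.08, test up). For fibroblast genes, at 3.06% ± 0.369 of MEF with LPA and 2.41% ± 0.0347 without, 2 of 18 rose, 1 fell and 15 did not pass (list alone 2 and 1, camera adjusted p = 0.22).

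The comparison called 4015 genes (2067 higher, 1948 lower), 3682 of them with no overlap between libraries. Of all tested genes 4774 had no overlap (chance share 10%). Set against DOX 72 h in place of the samples labelled DOX 48 h, chosen after the data were seen, Dusp4 was at -0.28, against 4.33 above. Dusp4, Cdx2 (0.22), Hoxd9 (0.10), Hoxa7 (0.08) and Axin2 (-0.87) no longer passed. The mean of the caudal and Hox list went from 2.07 to 0.30, and its call was lost, so the rise of that list with LPA depends on the samples labelled DOX 48 h. The Wnt response (-0.78) and formative (-1.14) lists also lost their calls, while the fibroblast (0.93) and p53 response (0.27) lists gained one.

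At 96 h, Hand1 averaged 349 ± 64.5 (SD, n = 3) with LPA and 1.97 ± 1.1 without, Rhox6 595 ± 76.7 against 10.7 ± 5.03, the Wnt ligand gene Wnt6 280.3 ± 49.1 against 2.23 ± 1.83, and Elf5, an ETS factor that maintains TSC, 62.6 ± 3.91 against 0.767 ± 0.666. Otx2 had 1.5 ± 0.656 against 163 ± 33.6 and Tdgf1 11.5 ± 5.64 against 580 ± 10.3. Hand1 rose by 6.93 ± 0.40, Wnt6 rose by 6.58 ± 0.32, Rhox6 rose by 5.75 ± 0.28, Rhox9 rose by 5.63 ± 0.27, Elf5 rose by 5.25 ± 0.35 and the keratin gene Krt7 rose by 4.14 ± 0.33 (SE, n = 3 and 3). Cdx2 rose by 1.33 ± 0.36. Otx2 fell by 6.05 ± 0.48, the Nodal inhibitor genes Lefty1 fell by 5.96 ± 0.33 and Lefty2 fell by 5.38 ± 0.36, Tdgf1 fell by 5.66 ± 0.50 and Fgf4 fell by 5.43 ± 0.50.

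In the trophoblast stem list 18 of 23 rose, none fell and 5 did not pass (list alone 18 and none, camera adjusted p = 3.0e-13). Of trophoblast differentiation genes, with Plac1 at 4.52 ± 0.43, Cebpa at 4.17 ± 0.45 and Dlx3 at 4.14 ± 0.57, 10 of 13 rose, 1 fell and 2 did not pass (list alone 11 and 1, camera adjusted p = 2.8e-06). H19 rose by 3.81 ± 0.30, Cdkn1c rose by 3.15 ± 0.27 and Phlda2 rose by 2.97 ± 0.28. Of placental imprinted genes 10 of 11 rose, 1 fell and none did not pass (list alone 10 and 1, camera adjusted p = 3.3e-06). For pluripotency none of 20 rose, 19 fell and 1 did not pass (list alone none and 19, camera adjusted p = 2.2e-17), and for the genes shared by ESC and TSC, where Esrrb fell by 2.1 ± 0.31 and Sox2 fell by 1.63 ± 0.20, none of 7 rose, 6 fell and 1 did not pass (list alone none and 6, camera adjusted p = 1.5e-04). Zic2 fell by 4.1 ± 0.42. For the formative list 3 of 11 rose, 6 fell and 2 did not pass (list alone 3 and 6, camera adjusted p = 0.18). Dusp4 fell by 3.0 ± 0.23, Spry4 fell by 2.36 ± 0.28 and Spry2 fell by 2.71 ± 0.41. For FGF/ERK response 5 of 13 rose, 8 fell and none did not pass (list alone 5 and 8, camera adjusted p = 0.025, and adjusted p = 0.097 with an estimated correlation). Gadd45a fell by 3.02 ± 0.18 and Myof rose by 2.11 ± 0.24. For YAP/TEAD targets 8 of 22 rose, 6 fell and 8 did not pass (list alone 10 and 6, camera adjusted p = 0.42). Hoxb8 fell by 3.29 ± 0.55 and Hoxa7 fell by 1.91 ± 0.47. In the caudal and Hox list 1 of 17 rose, 4 fell and 12 did not pass (list alone 1 and 3, camera adjusted p = 0.28). Mael, a germline gene of the piRNA pathway, fell by 3.77 ± 0.53. Of germline genes none of 6 rose, 4 fell and 2 did not pass (list alone none and 4, camera adjusted p = 0.013). Phlda3 rose by 1.8 ± 0.17 and Perp rose by 2.44 ± 0.20. For p53 response 5 of 12 rose, none fell and 7 did not pass (list alone 5 and none, camera adjusted p = 0.0042). Apoe fell by 3.23 ± 0.16. Of primitive endoderm genes 4 of 19 rose, 2 fell and 13 did not pass (list alone 4 and 2, camera adjusted p = 0.51, median 0.06, mean -0.04, test up). S100a4 rose by 2.16 ± 0.27 and Col1a1 rose by 2.79 ± 0.31, the fibroblast level being 3.15% ± 0.673 of MEF with LPA and 0.72% ± 0.252 without. In that list 13 of 18 rose, none fell and 5 did not pass (list alone 14 and none, camera adjusted p = 5.8e-06, and adjusted p = 0.066 with an estimated correlation). There were 3809 changed genes (1975 higher, 1834 lower), 3586 with no overlap between libraries. Of all tested genes 4922 had no overlap (chance share 10%).

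The LPA effects at both times were compared by a test of their difference. The cell cycle inhibitor gene Cdkn1c moved by 4.66 ± 0.38 more (SE, 12 libraries) at 96 h than at 48 h, Phlda2 by 4.52 ± 0.39 and Rhox6 by 4.36 ± 0.40. Saa3 (-8.6 ± 0.44), Dusp4 (-7.33 ± 0.32), the interferon-induced membrane protein gene Ifitm1 (-7.13 ± 0.36) and Sct (-6.5 ± 0.71) had lower effects at 96 h, and Cdx2 differed by -3.56 ± 0.52 (adjusted p = 3.5e-07). For this difference, rose means a higher and fell a lower LPA effect at 96 h. In the caudal and Hox list, with Hoxa7 at -5.11 ± 0.67, none of 17 rose, 11 fell and 6 did not pass (list alone none and 11, camera adjusted p = 1.1e-06). For placental imprinted genes, with Igf2 at -3.52 ± 0.35, 3 of 11 rose, 8 fell and none did not pass (list alone 3 and 8, camera adjusted p = 0.16). For fibroblast genes 9 of 18 rose, 1 fell and 8 did not pass (list alone 11 and 2, camera adjusted p = 0.0053, and adjusted p = 0.36 with an estimated correlation). For pluripotency none of 20 rose, 7 fell and 13 did not pass (list alone 2 and 8, camera adjusted p = 0.023, and adjusted p = 0.36 with an estimated correlation). Among trophoblast stem genes 8 of 23 rose, 4 fell and 11 did not pass (list alone 8 and 6, camera adjusted p = 0.48). The difference passed for 2329 genes (1166 higher, 1163 lower), or 1010 higher and 1314 lower with edgeR, so neither side was larger under all settings. With DOX 72 h as the early control, a later choice, it passed for 1355 and Cdx2, no longer past the threshold, was at 1.10. The caudal and Hox list went from a mean of -2.57 to -0.80 and the fibroblast list to 0.47, and both lost their calls, while the trophoblast differentiation list (1.44) gained one.

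Both LPA effects called 2080 genes in common, where 1479 would be shared by independent lists of those sizes. Of these, 1724 had the same sign and 356 opposite signs. Across genes, which are not independent replicates, the LPA effects at 48 h and 96 h had r = 0.424, from libraries that the other did not use. Set against the difference between established TSC and ESC, r across genes was 0.382 for LPA at 48 h, 0.597 for LPA at 96 h and 0.552 for LPA at 8 d. It was 0.557 for DOX 7 d against the samples labelled DOX 48 h, 0.358 for withdrawal against DOX 96 h and -0.125 for withdrawal against DOX 7 d, again with no shared library.

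The 8-day LPA samples had as their nearest control the samples with 4 days of DOX and 4 days without it. The labels do not say whether DOX was kept for all 8 days with LPA, so LPA and the DOX schedule cannot be separated here. Krt7 averaged 606 ± 54.7 against 44.5 ± 11.5 in the control (SD, n = 3 and 3), Rhox6 925 ± 134 against 84.9 ± 11.8 and the phospholipid flippase gene Atp11a 169 ± 11.6 against 11.8 ± 1.94. Otx2 had 0.20 ± 0.346 against 121 ± 12.4 and Trh 2.9 ± 1.47 against 439 ± 35.4. Cdx2 rose by 1.67 ± 0.36, Krt7 rose by 3.76 ± 0.33, Rhox9 rose by 3.35 ± 0.27 and Sct rose by 4.28 ± 0.50 (SE, n = 3 and 3). Among trophoblast stem genes 20 of 23 rose, none fell and 3 did not pass (list alone 20 and none, camera adjusted p = 3.2e-13). Among trophoblast differentiation genes, with Gjb2 at 3.99 ± 0.58, 10 of 13 rose, 1 fell and 2 did not pass (list alone 10 and 1, camera adjusted p = 3.2e-05). Otx2 fell by 6.7 ± 0.48, Sox3 fell by 4.98 ± 0.48 and Fgf15 fell by 4.46 ± 0.48. For the formative list none of 11 rose, 10 fell and 1 did not pass (list alone none and 10, camera adjusted p = 1.4e-07). Tdgf1 fell by 6.73 ± 0.50 and Gdf3 fell by 5.34 ± 0.46. For pluripotency 3 of 20 rose, 16 fell and 1 did not pass (list alone 3 and 16, camera adjusted p = 6.3e-08). Cubn fell by 3.76 ± 0.49, Amn fell by 3.17 ± 0.49 and Apoe fell by 3.91 ± 0.16. Of primitive endoderm genes 4 of 19 rose, 12 fell and 3 did not pass (list alone 4 and 12, camera adjusted p = 0.0092), a list that lost its call, with a camera direction that turned and a mean still negative at -0.31, among genes with a mean of 50 or more.

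Igf2 rose by 2.99 ± 0.25 and H19 rose by 2.34 ± 0.30. For placental imprinted genes 9 of 11 rose, 2 fell and none did not pass (list alone 9 and 2, camera adjusted p = 2.2e-04). Etv5 fell by 3.04 ± 0.18, Spry4 fell by 2.62 ± 0.28 and Fos rose by 2.66 ± 0.28. For FGF/ERK response 3 of 13 rose, 8 fell and 2 did not pass (list alone 3 and 8, camera adjusted p = 0.0066). Fjx1 fell by 3.12 ± 0.47 and Myof rose by 2.77 ± 0.24. For YAP/TEAD targets 14 of 22 rose, 3 fell and 5 did not pass (list alone 15 and 3, camera adjusted p = 0.0092, and adjusted p = 0.12 with an estimated correlation). Hoxc9 rose by 2.64 ± 0.48 and Hoxc6 rose by 2.52 ± 0.46. For caudal and Hox genes 11 of 17 rose, none fell and 6 did not pass (list alone 11 and none, camera adjusted p = 0.0012). Cdkn1a rose by 1.7 ± 0.17 and Ccng1 rose by 1.8 ± 0.37. For p53 response 6 of 12 rose, 1 fell and 5 did not pass (list alone 8 and 1, camera adjusted p = 0.0012). Col3a1 rose by 2.63 ± 0.27, the fibroblast level being 7.9% ± 0.22 of MEF with LPA and 2.52% ± 0.48 in the control. For fibroblast genes 14 of 18 rose, none fell and 4 did not pass (list alone 18 and none, camera adjusted p = 1.4e-07). Of all tested genes 5323 had no overlap between libraries (chance share 10%). The changed genes numbered 4283 (2212 higher, 2071 lower), 4063 of them with no overlap. With DESeq2 2087 were higher and 2163 lower.

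**Figure D3:**
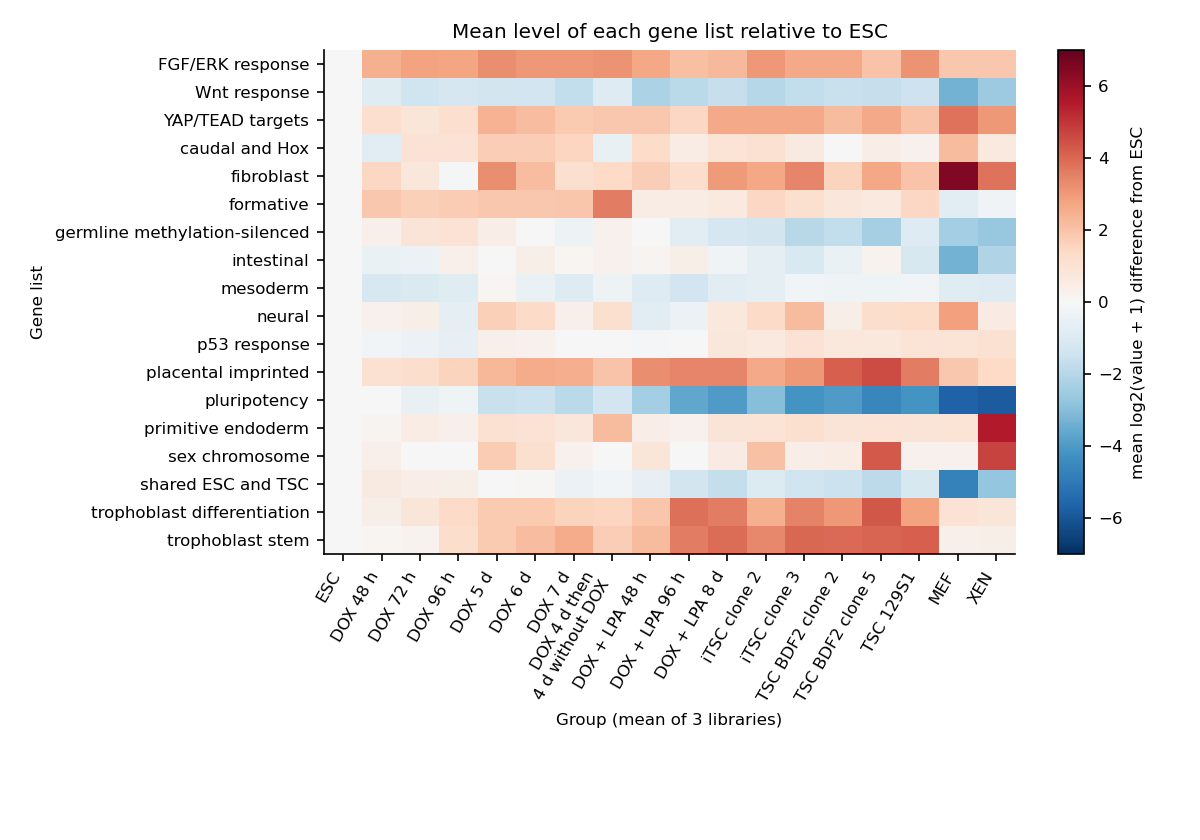
Mean log2(value + 1) difference from ESC of each of the 18 gene lists (vertical axis) in each group (horizontal axis, mean of 3 libraries), with colour as the difference. The trophoblast stem list reaches 3.89 in DOX + LPA 8 d and 2.6 in DOX 7 d.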

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

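Tests of how other splits of the libraries compare were set beforehand, and all tests of explanations for the 3 patterns below were chosen only after the result was seen. The results listed first are LPA effects that differed between 96 h and 48 h by a test of the difference itself. Each of the 18 groups had 3 libraries, too few for a test of a single library.

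The LPA effect differed for 2329 genes. Cdx2 was 4.88 at 48 h and 1.33 at 96 h (difference -3.56), Saa3 5.50 and -3.10 (-8.60), Dusp4 4.33 and -3.00 (-7.33) and Ifitm1 2.04 and -5.09 (-7.13). Effects that were higher at 96 h were Cdkn1c, -1.51 and 3.15 (difference 4.66), Phlda2, -1.54 and 2.97 (4.52), Hand1, 3.14 and 6.93 (3.79), and Krt7, 0.38 (not past the threshold) and 4.14 (3.76). These are log2 differences from limma over 12 libraries. They rest on the samples labelled DOX 48 h, whose Cdx2 level is weighed below. With DOX 72 h in their place, a control chosen after the result was seen, Cdx2 was at 1.10 and no longer passed, while the other 7 genes kept direction and call, with Saa3 at -5.45 and Dusp4 at -2.72.

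Other splits of the libraries into groups of the same sizes gave fewer changed genes in 16 comparisons. For established TSC against ESC, 1 of 100 splits, the real one, reached the real count of 5971 (highest other 3294). It was 1 of 84 for iTSC against ESC (5677, highest other 4285) and 1 of 100 for iTSC against established TSC (2578, highest other 1122). Libraries of a line resemble each other, and most of these splits mix lines, so they cannot decide whether chance is excluded. The lines, not the libraries, are the units of these 3 comparisons, and the splits of whole lines are too few for a share under 0.05. For the difference between LPA effects, 2 of 100 permutations of the residuals reached the real count of 2062, and the highest other gave 2491. The fit pooled the lines on each side into a single group, or for the LPA difference used 12 libraries, so real counts differ from those above where several lines or only 12 libraries entered. The remaining 13 comparisons had 1 of 10 splits reaching the real count, and splits that few cannot give a share under 0.05. Real counts and the highest others were, for DOX against ESC, 2842 and 29 (samples labelled 48 h), 3413 and 15 (72 h), 3525 and 51 (96 h), 4160 and 348 (5 d), 3812 and 27 (6 d) and 4188 and 3 (7 d). They were 2551 and 2 for DOX 7 d against the samples labelled DOX 48 h, 2408 and 12 for withdrawal against DOX 96 h, and 1268 and 14 for withdrawal against DOX 7 d. With LPA they were 4015 and 7 (48 h), 3809 and 2 (96 h) and 4283 and 6 (8 d), and for iTSC clone 3 against clone 2 they were 2370 and 19.

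Cdx2 was at the ESC level in the samples labelled DOX 48 h. The tables argue against too few reads, since 181.1 Cdx2 reads would be expected over the 3 libraries at the 72 h level (Poisson 95% range 155 to 208, which covers counting error only) and 6 were counted. The libraries had 1.5 ± 1.67 normalized counts against 57.1 ± 25.3 at 72 h (SD, n = 3). That the label is wrong and these cells had no induction may be the cause, since 1 of the 8 caudal and Hox genes higher at 72 h was higher in these samples. That reads of the transgene are not counted and the endogenous gene starts later cannot be decided, since no library shows the transgene alone. With LPA at 48 h Cdx2 was 61.7 ± 5.7, and 7 of these 8 genes were higher than without it. A biological delay was not tested, because no other group at 48 h lacks LPA.

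H19 was at 3468 to 4315 in DOX + LPA 48 h and at 279 to 364 in the later LPA libraries. The tables argue against RNA of established TSC, whose share would have to be 93.8% with BDF2 clone 2 as the source, where the median of 9 other abundant TSC genes was 6.36% (Krt8 5.86%, Rhox6 2.29%). With BDF2 clone 5 as the source, H19 needs 19.2% and the median of 18 genes was 5.65%, a smaller gap, so this argument is weaker for that line. They also argue against a single library as the source, since the lowest of the 3 had 3468. No biological explanation was tested.

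Of 18 fibroblast genes 13 passed as higher in iTSC than in established TSC and none as lower. The mean fibroblast level was 11% ± 0.71 of MEF in DOX 5 d and 0.72% ± 0.252 in DOX 96 h, which were not compared by a test of genes. Carryover of feeder fibroblasts with the profile of the MEF libraries would add the same percentage of the MEF level to each gene. In iTSC the listed genes at 500 or more in MEF needed from 1.25% (Col3a1) to 43.1% (S100a4), and in DOX 5 d from 3.57% (Col3a1) to 55.6% (S100a4), which argues against carryover as the whole cause. The collagen genes Col1a1, Col1a2 and Col3a1 needed at most 3.28% in iTSC, so for these carryover may contribute. Feeders with another profile than the MEF libraries were not tested, nor was a biological explanation.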

How the results depend on the processing

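Settings named as added were chosen only after the result was seen. Counts of changed genes stayed within 1.5 times the reported count for all 17 comparisons with both pseudocounts, no filter, TMM scaling, edgeR and DESeq2, and in 126 fits that each left out a library. With the replicate number as a block they did so as well, for example 4035 genes for LPA at 48 h. Pairing by replicate number had r from -0.11 to 0.27 in 13 comparisons, so the numbers show no pairing.

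Among genes with a mean of 50 or more, the counts were 2585 (established TSC against ESC), 1420 (samples labelled DOX 48 h against ESC), 1607, 1727, 1835, 1766 and 1888 (DOX at 72 h, 96 h, 5 d, 6 d and 7 d against ESC), 1301 (DOX 7 d against the samples labelled DOX 48 h), 2438 (iTSC against ESC), 1568 (iTSC against established TSC), 1381 and 733 (withdrawal against DOX 96 h and 7 d), 1944, 1885 and 1320 (LPA at 48 h, at 96 h and their difference), 2047 (LPA 8 d) and 1492 (clone 3 against clone 2). Fewer genes were tested there. A fit of only the libraries compared gave 627 for withdrawal against DOX 7 d and 1450 for clone 3 against clone 2, with fewer samples to estimate the spread. Line means gave 1 gene for iTSC against established TSC, with 5 values. The added control DOX 72 h gave 1355 for the difference between LPA effects, and the cause was not tested.

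List tests that turned direction were the formative list with LPA at 48 h (mean 0.46) and primitive endoderm with LPA at 8 d (-0.31), both among genes with a mean of 50 or more, and the mean of the latter was negative in both. Caudal and Hox genes turned at DOX 5 d (0.0106) and 7 d (0.18) without MEF-high genes, an added setting that removed 904 tested genes. None of these 4 lists passed after turning. With the added control DOX 72 h in place of the samples labelled DOX 48 h, named genes that turned were Dusp4 (-1.59) and Sp5 (0.10) for DOX 7 d, Dusp4 (-0.28) for LPA at 48 h and Cdx2 (1.10) for the difference between LPA effects. Of these, Dusp4 for DOX 7 d passed in the new direction, and the other 3 lost their call. The cause was not tested.

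Of the list tests under the alternatives, 4768 kept direction and side of the threshold, 71 lost the threshold, 82 gained it and 4 turned. For named genes these were 6151, 33, 6 and 4. List tests that lost and gained the threshold were 16 and 5 among genes with a mean of 50 or more, 5 and 11 with edgeR and 4 and 11 with DESeq2. Line means for iTSC against established TSC lost 25 named-gene calls and 1 list call, but list tests compare genes, not lines. Group positions on the axis moved by at most 0.0499 under settings chosen beforehand, and by at most 0.0418 when a library was left out. Which of the higher and lower counts was larger changed with a setting for established TSC against ESC, iTSC against ESC and against established TSC, withdrawal against DOX 7 d, LPA at 48 h and 8 d, the difference between LPA effects, and clone 3 against clone 2. Depth limits low genes, since 1 read was worth 0.389 to 2.51.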

Other observations

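MEF and XEN are on neither side of the 17 comparisons, and were tested against established TSC only to choose the 409 genes of the restricted axis. In XEN the fibroblast level was 17.5% ± 7.32 of MEF (SD, n = 3). Relative to ESC, the trophoblast stem list averaged 0.34 in MEF and 0.42 in XEN, and the primitive endoderm list 5.56 in XEN and 0.98 in MEF, on the log2 scale.

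Apoe, a lipid carrier gene of the primitive endoderm list, averaged 1301 ± 49.6 in ESC, 3914 ± 284 at DOX 72 h and 5271 ± 313 at DOX 96 h (SD, n = 3). It was singled out after its values were seen. It stood at 4195 ± 326 in DOX + LPA 48 h, 563 ± 65 in DOX + LPA 96 h and 118 ± 33.1 in DOX + LPA 8 d.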
